A study of Mus musculus with 6 samples.

How the data were processed

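Single cells were prepared from the pancreatic lymph nodes of 6 mice and loaded on the droplet platform of 10x Genomics, which tags the RNA of each cell with a cell barcode and each captured molecule with a unique molecular identifier (UMI). The labels describe 3 mice that carried a floxed gene without the CD4-Cre transgene (here Cre-negative 1 to 3) and 3 that carried it with CD4-Cre (Cre-positive 1 to 3). Cre recombinase removes the DNA between loxP sites, and CD4-Cre is used to do so in T cells, which pass through a stage that expresses Cd4 whether they become CD4 or CD8 cells. The labels used here give no strain, sex or age, and do not say which part of the gene is floxed. The floxed gene and some other genes are not reported here. Each library is a separate mouse per the labels' protocols.

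The deposited values were raw UMI counts per gene and cell barcode, made by the authors with Cell Ranger 6.1.2 on the mouse genome build mm10, per the submitters' processing notes. The annotation release behind the 31053 features was not given in the sources used here. Gene positions were looked up by Ensembl identifier in GENCODE M21, which is on the same build, and 30934 features had a match. No file names cell types, so these were rebuilt from the counts.

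The libraries held 8209 to 10936 barcodes and 59680 in all. Barcodes with under 500 UMIs, under 300 genes or over 10% mitochondrial UMIs were left out. Doublets were scored with Scrublet within scanpy 1.11.5, and the highest-scoring cells were removed at a rate of 0.8% per 1000 barcodes, which took 480 to 914 cells per library. The tool's own threshold would have taken 183 to 451. The 51777 cells kept had a median of 4239 to 5596 UMIs per library and a median mitochondrial share between 3.91% and 4.83%.

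Cells were clustered on 2000 variable genes without antigen receptor segments, ribosomal, mitochondrial and sex-linked genes. The clustering used all 56310 cells that passed the UMI, gene and mitochondrial limits. Cells called doublets thus took part in it and were removed afterwards. All cells were clustered with 30 principal components at a resolution of 1.0, and T cells again with 20 components at 1.5, using 20 neighbours and the Leiden method (leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0). Clusters were named from marker genes, and a T cell cluster that mixed CD4 and CD8 cells, was led by nuclear RNA or had low depth stayed unnamed. Low-depth clusters of migratory and of plasmacytoid dendritic cells were named. Unnamed T clusters held 7.31% ± 0.376 of T cells in Cre-negative and 6.36% ± 1.26 in Cre-positive mice (mean ± SD, n = 3). Cells of CD4 or regulatory clusters with a Cd8a or Cd8b1 UMI, and cells of CD8 clusters with a Cd4 UMI, were left out of the classes, which took 205 to 302 cells per library.

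UMI counts were summed per mouse over the cells of a class, since cells of 1 mouse are not replicates. The sums covered 2611 to 3633 conventional CD4 T cells per mouse, 389 to 545 regulatory T cells, 1260 to 2035 CD8 T cells and 1390 to 2709 B cells. Activated or memory cells were tested also on their own, with 203 to 368 CD4 and 131 to 212 CD8 cells per mouse. The 3 Cre-positive sums were compared with the 3 Cre-negative sums of a class with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM factors, its low-count filter, robust dispersions and Benjamini-Hochberg adjustment at 0.05. Log2 fold changes are Cre-positive over Cre-negative. The standard error (SE) given with them is the size of the fold change over the square root of its F statistic. For genes near 0 in 1 group or class it is no measure of precision. Levels are CPM, the UMI counts of a gene relative to the scaled total of the class, as mean ± SD over 3 mice. Differences of the genotype effect between classes were tested as an interaction over 12 sums with the mouse as a block.

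Gene lists were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, for lists with at least 5 tested members in each of the 4 main classes, and adjusted over all 139 tests. Beside it camera was run with an estimated correlation, and fry. The design, the 40 lists of pathways, cell type markers and signs of RNA quality, and the rule for named genes were written before the data were examined. The rule names the floxed gene and the sex-linked genes, then up to 12 risen and 12 fallen genes per class that pass and do not overlap between groups, at 5 CPM or more and without receptor segments or predicted models. Where fewer than 10 pass, the 10 genes of smallest p are named and said not to pass, and 4 members of smallest p per list that passes, of which the text prints a selection. Shares of cells were compared per mouse with exact two-sided permutation tests, and 3 mice against 3 cannot give a p below 0.1.

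Simulated counts were drawn gene by gene from the real means, library sizes and fitted dispersions, with 200 changed genes at 5 CPM or more. So many changed genes ease the adjusted threshold, and lower genes were not covered, so recovery in the real comparisons may be lower. The test recovered 100% of rises by 2-fold in conventional CD4 T and B cells, 88% in regulatory and 98% in CD8 T cells. It recovered 76% in activated or memory CD4 T cells and 86% in activated or memory CD8 T cells. Falls to 0.5-fold were recovered at 100% in conventional CD4 T and B cells, 98% in CD8 T cells, 66% in regulatory T cells, 62% in activated or memory CD4 and 54% in activated or memory CD8 T cells. Unchanged genes called were 16 in conventional CD4, 6 in regulatory, 13 in CD8, 13 in B, 12 in activated or memory CD4 and 5 in activated or memory CD8 T cells. Rises by 1.5-fold were recovered less often in the smaller classes, with 60% in regulatory T cells and 38% in each activated or memory class. For the interactions 96% of the rises by 2-fold were recovered between conventional CD4 T and B cells and 99% between conventional CD4 and CD8 T cells, with 18 and 10 unchanged genes called.

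Libraries of a group differed from each other by far more than counting error, with a chi-square per gene between 5.81 and 34.9, and were counted as separate mice. Intervals for shares of cells are Clopper-Pearson at 95%, and a share of 0 is given with the limit that 3 cells allow; both cover counting error only. Alternatives covered another normalization (RLE), the Wald test of DESeq2 1.42.0, no low-count filter, the replicate number as a block, each mouse left out, doublets kept, at most 5% mitochondrial UMIs, at least 2000 UMIs per cell, the same number of cells per mouse, receptor segments left out, and gates on Cd4, Cd8 and Foxp3 UMIs in single cells. Chosen after seeing the data were keeping the cells with both Cd4 and Cd8 UMIs, leaving out the clusters led by immediate early genes, and leaving out 1 cluster of B cells. Values were computed with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots with matplotlib 3.10.9.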

Results

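CD4-Cre deletes floxed DNA in T cells, and the study used it to ask how a gene acts within these cells in relation to autoimmune disease. Gene expression was measured cell by cell in pancreatic lymph nodes, which drain the pancreas, of 3 mice with the floxed gene alone (Cre-negative) and 3 that also carried CD4-Cre (Cre-positive). The Cre-negative libraries held 47149014, 48614018 and 51499167 UMIs, and the Cre-positive libraries 52857382, 61321105 and 58420889. After filtering there were 6834, 8016 and 9069 cells from Cre-negative mice 1 to 3 and 9529, 9498 and 8831 from Cre-positive mice 1 to 3. They included 19292 conventional CD4 T cells, 2722 regulatory T cells, 9553 CD8 T cells and 12190 B cells. B cells do not express Cd4 and served as a class outside the targeted lineage.

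The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were expressed at alike levels in both groups. In conventional CD4 T cells Ddx3y had 113 ± 11.5 CPM in Cre-negative and 110 ± 6.03 CPM in Cre-positive mice (SD, n = 3), and Eif2s3y had 127 ± 10.7 and 122 ± 2.67 CPM. Xist, the RNA of the inactive X chromosome, had 0.396 ± 0.344 and 0.412 ± 0.253 CPM. None of the 4 Y-linked genes passed the test in any of the 4 main classes, and Xist fell under the low-count filter there.

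**Figure D1:**
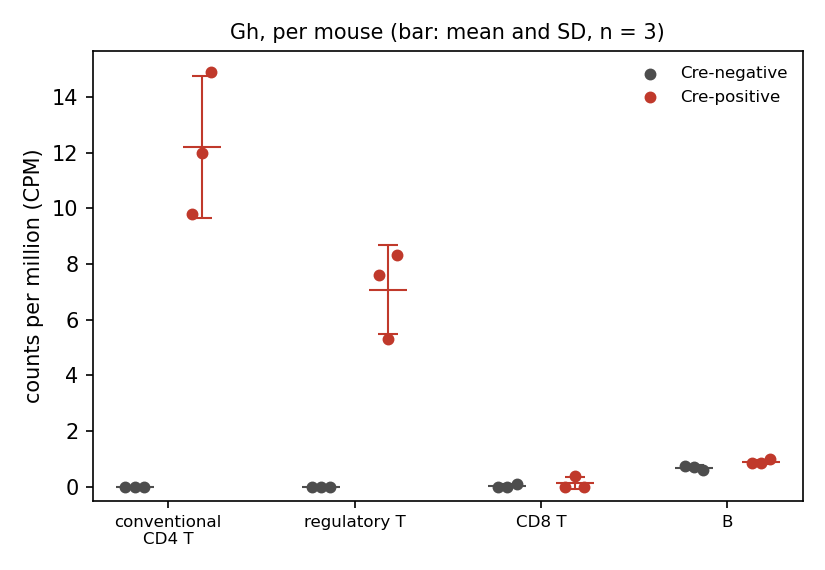
Gh levels in CPM on the vertical axis, for conventional CD4 T cells, regulatory T cells, CD8 T cells and B cells along the horizontal axis. Each point is 1 mouse, and bars give the mean and SD of the 3 Cre-negative and the 3 Cre-positive mice; Gh stood at 0 in every Cre-negative sum of CD4 cells and at 9.81 to 14.9 CPM in the Cre-positive sums of conventional CD4 T cells.

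In conventional CD4 T cells Gh and Pmepa1 rose in Cre-positive mice. Gh, which encodes pituitary growth hormone (ENSMUSG00000020713, chromosome 11, 106300271 to 106301865), had 0 UMIs in each Cre-negative mouse and 140, 234 and 262 UMIs in Cre-positive mice 1 to 3. Its level was 12.2 ± 2.55 CPM (SD, n = 3, adjusted p = 4.02e-09). With UMIs summed over each group it was at least 193-fold above the floor of 3 UMIs over the Cre-negative group. Pmepa1 (ENSMUSG00000038400, chromosome 2, 173224458 to 173276533), a gene induced by TGF-beta that dampens TGF-beta signalling, rose from 17.6 ± 2.40 to 26.6 ± 0.783 CPM (log2 fold change 0.60, SE 0.0939, adjusted p = 0.0121). A UMI of Gh was found in 6.05% of Cre-positive cells (617 of 10195, 95% Clopper-Pearson interval 5.60% to 6.53%) and in 0 of 9097 Cre-negative cells, which allows up to 0.0330%. In B cells, which lack Cd4 transcription, the share was 0.394% in Cre-positive and 0.334% in Cre-negative mice, at medians of 4273 and 4519 UMIs. Pmepa1 lost its call without Cre-negative 1 (adjusted p = 0.0676), at 5% mitochondrial UMIs (0.205) and with gates on single cells (0.0760), and its highest adjusted p over 18 alternatives was 0.205.

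Among 11331 genes tested in conventional CD4 T cells these were the 2 that passed, both higher. An unadjusted p under 0.05 was met by 529 (4.67%), where chance alone gives a share of about 0.05. In the other classes this share lay between 4.18% and 5.25%. The groups did not overlap for 10.5% of genes, where chance gives 10%. The count was 1 without Cre-negative 1, 4 without Cre-negative 3 and 14 without Cre-positive 3, and 5 with DESeq2. The next genes by p did not pass. The phosphatase gene Ppm1l stood at 10.6 and 6.74 CPM (adjusted p = 0.0775), and Tnfaip3, which encodes the NF-kB inhibitor A20, at 450 ± 60.7 and 341 ± 10.1 CPM (0.148). Tnfaip3 passed without Cre-negative 3 (adjusted p = 0.0267) and with DESeq2 (0.0166), in a range from 0.00152 to 0.595 over 18 alternatives. Log2 fold changes were -0.38 for the nuclear import gene Kpna4, -0.36 for the transcription factor gene Maff, 0.34 for Trim59, -0.58 for Tsc22d1 and -0.50 for Mtmr10. Adjusted over the list alone, Pmepa1 passed in the TGF-beta response genes (3.85e-05), and Tnfaip3 in the T cell activation genes (0.00395).

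As groups, interferon-response and memory genes lay higher in Cre-positive conventional CD4 T cells and naive-cell genes lay lower. List calls here and below rest on the preset correlation. With it, every other split of the 6 mice into 3 against 3 also gave at least 17 calls over the 4 main classes. Of 48 type I interferon response genes 39 were higher (camera adjusted p = 2.05e-04; adjusted p = 0.681 with an estimated correlation), with log2 fold changes of 0.27 for Bst2, 0.29 for Irf7, 0.22 for Herc6 and 0.25 for Ly6a. Of 34 interferon-gamma response genes 28 were higher (8.41e-04; 0.661 with an estimated correlation), among them the GTPase gene Igtp at 0.31. Memory and migration genes were higher in 21 of 28 cases (0.00204; 0.661 with an estimated correlation), with 0.34 for S100a11, 0.58 for the chemokine receptor gene Cxcr6 and 0.89 for Anxa1. Naive and quiescence genes were lower in 21 of 24 cases (2.64e-04; 0.661 with an estimated correlation), with -0.21 for Satb1, -0.20 for Lef1, -0.18 for the egress receptor gene S1pr1 and -0.17 for the homing receptor gene Ccr7. The naive call held in the 14 alternatives that kept camera at the preset correlation. It was lost with the estimated correlation and with fry. The type I interferon call was lost without Cre-negative 3 (0.0905) and Cre-positive 1 (0.479), the interferon-gamma call without Cre-positive 1 (0.379) and the memory call without Cre-negative 1 (0.119). Cre-positive 1 also had the highest share of interferon-led clusters, 7.29% of its T cells against 3.8% to 4.44% in the other mice, and the highest share of activated or memory cells, which are part of these sums, 11.58% of its conventional CD4 T cells against 5.69% to 7.93%. Naive clusters not led by interferon or immediate early genes held 78.7% ± 2.88 of Cre-negative and 72.7% ± 4.76 of Cre-positive conventional CD4 T cells (SD, n = 3, exact permutation p = 0.1). The sums pool all clusters of the class. So a shift in cluster makeup cannot be told apart here from a change of levels within cells.

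The class II antigen presentation genes were lower in conventional CD4 T cells in 8 of 11 cases (camera adjusted p = 0.00219; adjusted p = 0.661 with an estimated correlation). H2-Eb1 had a log2 fold change of -0.33 and passed when adjusted over the list alone (0.0394), and H2-Aa stood at -0.31, Cd74 at -0.29 and H2-DMb2 at -0.51. B cell markers moved with them, with 14 of 18 lower (0.00334; adjusted p = 0.661 with an estimated correlation). These genes are abundant in B cells, and whether their UMIs in T cells are free RNA from other cells was not tested. A Cd74 UMI was found in 20.2% of Cre-negative and 16.6% of Cre-positive conventional CD4 T cells and in 20.6% and 17.9% of CD8 T cells. For the B cell receptor gene Cd79a the shares were 3.75% and 3.35% in conventional CD4 T cells and 3.76% and 3.66% in CD8 T cells, at median depths of 4907 and 4761 UMIs in the former and 6192.5 and 5813 in the latter. The class II call was lost without Cre-negative 2 (0.0983) and Cre-positive 2 (0.103), and the B marker call without Cre-positive 2 (0.648).

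A further 6 lists passed in conventional CD4 T cells, each with calls lost on leaving out 1 or more mice. Heat shock genes were higher in 12 of 15 cases (camera adjusted p = 0.00955; adjusted p = 0.663 with an estimated correlation), MYC and nucleolar genes in 23 of 31 (0.0137; 0.661), oxidative phosphorylation genes in 57 of 73 (0.0224; 0.95), cholesterol synthesis genes in 18 of 23 (0.0361; 0.626) and T cell markers in 12 of 14 (0.0487; 0.681). All 13 mitochondrially encoded genes were lower (0.0484; 0.751). Without Cre-negative 1 the adjusted p was 0.349 for MYC, 0.204 for oxidative phosphorylation, 0.155 for cholesterol and 0.537 for T cell markers. Without Cre-negative 2 it was 0.264 for heat shock, 0.0682 for cholesterol and 0.427 for mitochondrial genes, and without Cre-negative 3 it was 0.0622 for the latter. Without Cre-positive 1 it was 0.427 for T cell markers and 0.117 for mitochondrial genes, and without Cre-positive 2 it was 0.196 for heat shock, 0.0720 for MYC and 0.851 for mitochondrial genes. Without Cre-positive 3 it was 0.114 for heat shock, 0.724 for oxidative phosphorylation and 0.269 for cholesterol. The oxidative phosphorylation list turned to lower without Cre-negative 1 and without Cre-positive 3. At 5% mitochondrial UMIs it stood at 0.0652, T cell markers at 0.0615 and mitochondrial genes at 0.140. Without the immediate early clusters oxidative phosphorylation stood at 0.0552, and T cell markers stood at 0.0518 with doublets kept and 0.0539 with the replicate block.

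In regulatory T cells, the Foxp3-expressing CD4 cells that restrain immune responses, Gh was the 1 gene of 8897 that passed, with 440 at an unadjusted p under 0.05. It had 0 UMIs in Cre-negative and 45 in Cre-positive mice, a level of 7.08 ± 1.59 CPM (SD, n = 3, adjusted p = 7.54e-04), and with UMIs summed over each group it was at least 14.4-fold above the floor over the Cre-negative group. The gene lies under the minimum level for named genes in this class and is named here after its values were seen. It was too low to be tested at 5% mitochondrial UMIs, and without Cre-positive 3 the count of genes was 4. None of the next genes passed. Tnfaip3 stood at 911 ± 134 and 683 ± 35.7 CPM (adjusted p = 0.352), the repair factor gene Areg at 28.4 and 16.7 CPM, the glycolytic enzyme gene Tpi1 at 27.2 and 43.4 CPM, and Zc3h12a, whose product degrades inflammatory mRNAs, at 90.1 and 64.5 CPM. Log2 fold changes were 1.83 for Lxn, -0.43 for Kpna4, 0.89 for Magohb, -0.65 for Pced1b, 0.73 for Cyb5r4 and 0.32 for the splicing factor gene Mbnl1. The groups did not overlap for 10.9% of genes, where chance gives 10%. Adjusted over the list alone, Tnfaip3 passed in the T cell activation genes (0.00407).

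Homing, quiescence and activation genes lay lower in Cre-positive regulatory T cells. Naive and quiescence genes were lower in 21 of 24 cases (camera adjusted p = 4.35e-05; adjusted p = 0.626 with an estimated correlation), with log2 fold changes of -0.40 for Klf3 and -0.29 for S1pr1. Chemokine and homing receptor genes were lower in 14 of 16 cases (9.21e-04; 0.626 with an estimated correlation), with Ccr8, a receptor of tissue regulatory T cells, at -0.94 and Ccr9, a gut homing receptor, at -0.65. Adjusted over the list alone, Ccr8 (0.0150) and S1pr1 (0.0436) passed. Both list calls held in the 14 alternatives with camera at the preset correlation, though leaving out the immediate early clusters removed no regulatory T cells. Both were lost with the estimated correlation and with fry. Glucocorticoid response genes were lower in 9 of 12 cases (4.96e-04; 0.661 with an estimated correlation), with Klf9 at -0.50 (0.0252 adjusted over the list alone) and Tsc22d3 at -0.31. This call was lost without Cre-negative 1 (0.0592) and Cre-positive 1 (0.236). T cell activation genes were lower in 21 of 31 cases (0.00617; 0.626 with an estimated correlation), with Nr4a3 at -0.44, Nfkbid at -0.41 and Egr1 at -0.40, and lost the call at 5% mitochondrial UMIs (0.0668). MYC and nucleolar genes were higher in 23 of 31 cases (0.00176; 0.661 with an estimated correlation), a call lost without Cre-negative 1 (0.189) and at 5% mitochondrial UMIs (0.0752).

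Regulatory T cell genes, among them Lag3 (log2 fold change -0.54), Lrrc32 (-0.36) and Gpr83 (-0.27), were lower in 19 of 26 cases (camera adjusted p = 0.0389; adjusted p = 0.661 with an estimated correlation). The call was lost without Cre-negative 1 (0.376), Cre-negative 2 (0.207), Cre-positive 1 (0.122) and Cre-positive 2 (0.0977), at 5% mitochondrial UMIs (0.413) and at 2000 UMIs per cell (0.0571). TGF-beta response genes were lower in 14 of 17 cases (0.0224; 0.661 with an estimated correlation), with Smurf2 at -0.38 and Pmepa1 at -0.16. That call was lost without Cre-negative 1 (0.0811), Cre-negative 2 (0.0767) and Cre-positive 1 (0.300), at 5% mitochondrial UMIs (0.302) and with doublets kept (0.0518). Oxidative phosphorylation genes were higher in 55 of 73 cases (0.00204; 0.860 with an estimated correlation), which was lost without Cre-negative 1 (0.947) and Cre-positive 3 (0.993) and at 5% mitochondrial UMIs (0.0668). The lists of inhibitory receptors, immediate early genes, type 2 helper genes, JAK-STAT signalling and heat shock genes also passed, with adjusted p from 0.0153 to 0.0283 and, with an estimated correlation, adjusted p from 0.626 to 0.681. All but heat shock genes were lower. Without Cre-negative 1 the adjusted p was 0.0984 for inhibitory receptors, 0.307 for type 2 helper, 0.265 for JAK-STAT and 0.221 for heat shock genes, and without Cre-negative 2 it was 0.243 for inhibitory receptors and 0.128 for JAK-STAT. Without Cre-negative 3 it was 0.0641 for inhibitory receptors and 0.163 for immediate early genes, and without Cre-positive 1 it was 0.316 for inhibitory receptors and 0.109 for JAK-STAT. Type 2 helper and heat shock genes were lost without Cre-positive 2 (0.0795 and 0.208) and Cre-positive 3 (0.114 and 0.0945), and JAK-STAT also without Cre-positive 3 (0.138). At 5% mitochondrial UMIs the adjusted p was 0.155 for immediate early genes, 0.0817 each for inhibitory receptors and JAK-STAT and 0.0712 for heat shock genes, and without the low-count filter it was 0.135 for inhibitory receptors and 0.735 for type 2 helper genes.

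In CD8 T cells Trim59 and Lxn rose and Tnfaip3 and Tiparp fell in Cre-positive mice. Trim59, a ubiquitin ligase gene (ENSMUSG00000034317, chromosome 3, 69035288 to 69044755), rose from 31.2 ± 3.70 to 50.6 ± 3.52 CPM (SD, n = 3; log2 fold change 0.70, SE 0.0952, adjusted p = 2.23e-04). Tnfaip3 (ENSMUSG00000019850, chromosome 10, 19000910 to 19015657) fell from 293 ± 43.5 to 202 ± 13.9 CPM (-0.53, SE 0.0933, adjusted p = 0.0200). Tiparp, an ADP-ribosyltransferase gene induced by the aryl hydrocarbon receptor (ENSMUSG00000034640, chromosome 3, 65528410 to 65555518), fell from 52.8 ± 2.00 to 38.2 ± 2.08 CPM (-0.46, SE 0.0861, adjusted p = 0.0204). Lxn, which encodes the carboxypeptidase inhibitor latexin (chromosome 3, 67457998 to 67463926), rose from 0.352 ± 0.0482 to 1.71 ± 0.252 CPM (2.24, SE 0.448, adjusted p = 0.0470). Lxn lies under the minimum level for named genes and is named after its values were seen. Trim59 held in 18 of 18 alternatives. Tnfaip3 was lost without Cre-negative 1 (adjusted p = 0.157), Cre-negative 2 (0.127) and Cre-positive 1 (0.0807). Tiparp was lost without Cre-negative 1 (0.0978), Cre-negative 2 (0.127), Cre-negative 3 (0.0863), Cre-positive 1 (0.0979) and Cre-positive 3 (0.0559), with DESeq2 (0.0799) and at 5% mitochondrial UMIs (0.139). Lxn was lost without each mouse but Cre-positive 3 (0.113 to 0.390), with DESeq2 (1.00), at 5% mitochondrial UMIs (0.0648) and without the immediate early clusters (0.306).

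These 4 genes were what passed among 10527 tested in CD8 T cells. All but Tnfaip3 lie between 60 and 70 Mb of chromosome 3. An unadjusted p under 0.05 was met by 553, and groups did not overlap for 10.3% of genes, where chance gives 10%. With DESeq2 2 genes passed. The count was 1 without Cre-negative 1, Cre-negative 2 or Cre-positive 1, 2 without Cre-negative 3, 7 without Cre-positive 2 and 11 without Cre-positive 3. The next genes by p did not pass. Kpna4 stood at 211 and 167 CPM and the interferon-induced GTPase gene Ifi47 at 129 and 161 CPM (adjusted p = 0.320 each). Log2 fold changes were 0.66 for Acot7, -0.48 for Papolg, 0.44 for D1Ertd622e, 0.50 for Nab2 and -0.44 for Tdg.

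**Figure D2:**
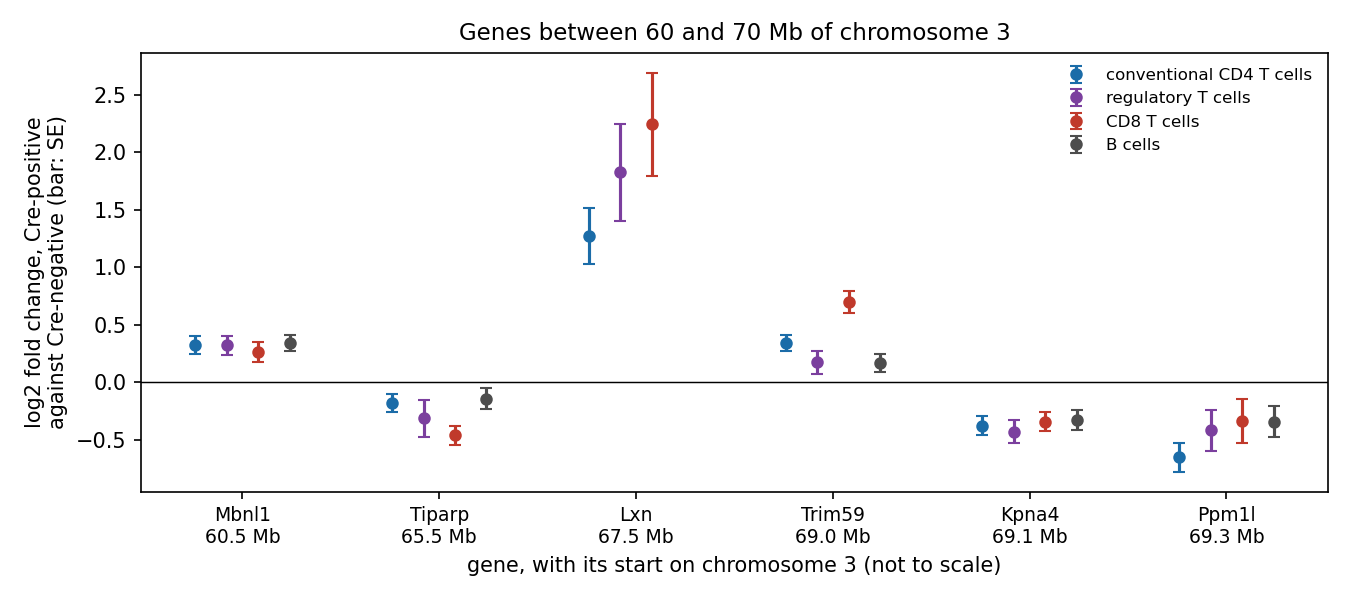
Log2 fold changes of Cre-positive over Cre-negative mice on the vertical axis, for Mbnl1, Tiparp, Lxn, Trim59, Kpna4 and Ppm1l in their order on chromosome 3 along the horizontal axis. Points are the 4 main classes and bars the SE derived from the F statistic. Lxn was not tested in B cells, and Mbnl1 lay between 0.26 and 0.34 in all 4 classes.

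CD8 T cells of Cre-positive mice had higher interferon-gamma response, glycolysis, MYC and heat shock genes as groups. Interferon-gamma response genes were higher in 29 of 32 cases (camera adjusted p = 1.97e-04; adjusted p = 0.661 with an estimated correlation), and the cytokine signalling inhibitor gene Socs1, at a log2 fold change of 0.31, passed when adjusted over the list alone (0.0307). Glycolysis and hypoxia genes were higher in 18 of 25 cases (8.41e-04; 0.661 with an estimated correlation), with 0.36 for Tpi1, 0.26 for Pgam1, 0.76 for the hexokinase gene Hk2 and 0.30 for the glucose transporter gene Slc2a1. MYC and nucleolar genes were higher in 24 of 31 cases (7.06e-04; 0.626 with an estimated correlation) and heat shock genes in 13 of 15 (1.23e-04; 0.661 with an estimated correlation), with 0.25 for Hsp90ab1. The glycolysis, MYC and heat shock calls held in the 14 alternatives with camera at the preset correlation. They were lost with the estimated correlation and with fry. The interferon-gamma call was also lost without Cre-positive 1 (0.169). Type I interferon response genes were higher in 36 of 47 cases (0.00346; 0.748 with an estimated correlation), with 0.32 for Bst2 and 0.33 for Isg15, which was lost without Cre-negative 3 (0.191) and Cre-positive 1 (0.997).

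Naive and quiescence genes were lower in CD8 T cells in 20 of 24 cases (camera adjusted p = 0.0114; adjusted p = 0.681 with an estimated correlation), with Ccr7 at a log2 fold change of -0.23 and Satb1 at -0.17. Immediate early genes, which cell handling also induces, were higher in 17 of 24 cases (0.00544; 0.748 with an estimated correlation), and Socs3 at 0.32 passed when adjusted over the list alone (0.0249). Cre-positive 3 stood apart here: clusters led by immediate early genes held 43.2% of its CD8 T cells against 8.28% to 17.8% in the other mice. Naive clusters not led by interferon or immediate early genes held 73.4% ± 4.54 of Cre-negative and 58.2% ± 14.6 of Cre-positive CD8 T cells (SD, n = 3, exact permutation p = 0.1), with 41.4% in Cre-positive 3. Since the sums pool these clusters, their makeup cannot be told apart from levels within cells. Without Cre-positive 3 the adjusted p was 0.764 for immediate early genes, 0.287 for naive genes and 0.882 for oxidative phosphorylation genes, which had been higher in 57 of 73 cases (0.0167; 0.95 with an estimated correlation). Without Cre-negative 1 these were 0.0797, 0.155 and 0.405, and without Cre-negative 2 it was 0.138 for naive genes. The oxidative phosphorylation list turned to lower without Cre-positive 3 and without Cre-negative 1. Without the immediate early clusters it stood at 0.0598 and the immediate early list at 0.445. Class II genes were lower in CD8 T cells in 8 of 9 cases (0.0123; 0.661 with an estimated correlation), which was lost without Cre-negative 2 (0.109) and Cre-positive 2 (0.440), with doublets kept (0.492) and at 5% mitochondrial UMIs (0.201).

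In B cells, the class outside the targeted lineage, Fcrl5 rose in Cre-positive mice. Fcrl5, an Fc receptor-like gene of B1 and marginal zone B cells (ENSMUSG00000048031, chromosome 3, 87435773 to 87500678), rose from 14.5 ± 0.569 to 23.2 ± 2.09 CPM (SD, n = 3; log2 fold change 0.67, SE 0.109, adjusted p = 0.0313). It was the 1 gene of 10515 that passed, with 545 at an unadjusted p under 0.05 and groups that did not overlap for 10.7% of genes, where chance gives 10%. Genes that did not pass were Mpeg1, the pore-forming perforin-2 gene of phagocytes, at 5.95 and 11.1 CPM (adjusted p = 0.0673), Mbnl1 at 553 ± 2.48 and 702 ± 12.3 CPM (0.241) and the inhibitory receptor gene Btla at 136 and 105 CPM. Mpeg1 passed without Cre-negative 2 (0.0403, in a range from 1.23e-04 to 0.845) and Mbnl1 without Cre-negative 1 (0.0479, in a range from 1.84e-04 to 0.607). Log2 fold changes were -0.45 for Lgals3, 0.56 for Tmem109, -0.80 for Cox15, -0.48 for Maf, -0.54 for Plk2 and 0.34 for Ppa1, and Tnfaip3 at -0.39 passed when adjusted over the T cell activation list alone (0.0213). Fcrl5 lost its call without Cre-negative 2 (0.0826), Cre-negative 3 (0.173), Cre-positive 1 (0.137) and Cre-positive 2 (0.0578), at 5% mitochondrial UMIs (0.885) and with the same number of cells per mouse (0.208), in a range up to 0.921. That highest value came without 1 cluster of B1-like or memory-like cells, where the log2 fold change fell from 0.67 to 0.24 (SE 0.127). This cluster held 3.02%, 4.41% and 4.09% of B cells in Cre-negative mice 1 to 3 and 6.90%, 5.25% and 5.64% in Cre-positive mice 1 to 3 (exact permutation p = 0.1), and had been formed with Fcrl5 among its genes. The count of genes was 5 with DESeq2, 4 without Cre-negative 1, 2 without Cre-negative 2 or Cre-positive 2, 6 without Cre-positive 3 and 0 without Cre-negative 3 or Cre-positive 1.

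MYC, heat shock, cholesterol synthesis, interferon-gamma and plasma cell genes lay higher in Cre-positive B cells. Interferon-gamma response genes were higher in 26 of 31 cases (camera adjusted p = 2.30e-06; adjusted p = 0.661 with an estimated correlation), and Irf1 at a log2 fold change of 0.34 and Socs1 at 0.43 passed when adjusted over the list alone. MYC and nucleolar genes were higher in 28 of 31 cases (2.30e-06; 0.451 with an estimated correlation) and heat shock genes in 11 of 13 (8.04e-06; 0.626 with an estimated correlation). Plasma cell markers were higher in 9 of 10 cases (7.07e-05; 0.626 with an estimated correlation), with Ighg1, an antibody heavy chain, at 1.02 and Derl3 at 0.70. Cholesterol synthesis genes were higher in 18 of 22 cases (1.85e-04; 0.661 with an estimated correlation), with Cyp51 at a log2 fold change of 0.57. These 5 calls held in the 14 alternatives with camera at the preset correlation, though leaving out the immediate early clusters removed no B cells. All 5 were lost with the estimated correlation and with fry. Leaving out the B1-like or memory-like cluster was not run for lists. All 13 glucocorticoid response genes were lower (3.81e-04; 0.626 with an estimated correlation), with Ddit4 at -0.42 and Il7r at -0.57, which was lost at 5% mitochondrial UMIs (0.0611). Oxidative phosphorylation genes were higher in 64 of 73 cases (4.18e-04; 0.840 with an estimated correlation), a call lost without Cre-negative 1 (0.843) and Cre-positive 3 (0.290). The naive, immediate early and follicular helper lists were lower with adjusted p from 0.0182 to 0.0232 and, with an estimated correlation, adjusted p from 0.661 to 0.681. Without Cre-negative 1 the naive list stood at 0.197 and the immediate early list at 0.0592, without Cre-negative 2 the follicular helper list at 0.112, and without Cre-negative 3 the immediate early list at 0.0528. Without Cre-positive 1 the 3 lists stood at 0.480, 0.571 and 0.170, without Cre-positive 2 the immediate early and follicular helper lists at 0.309 and 0.0611, and without Cre-positive 3 the naive list at 0.0573. At 5% mitochondrial UMIs the 3 lists stood at 0.978, 0.0767 and 0.0611, and with doublets kept the immediate early list stood at 0.0515 and the follicular helper list at 0.0619.

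**Figure D3:**
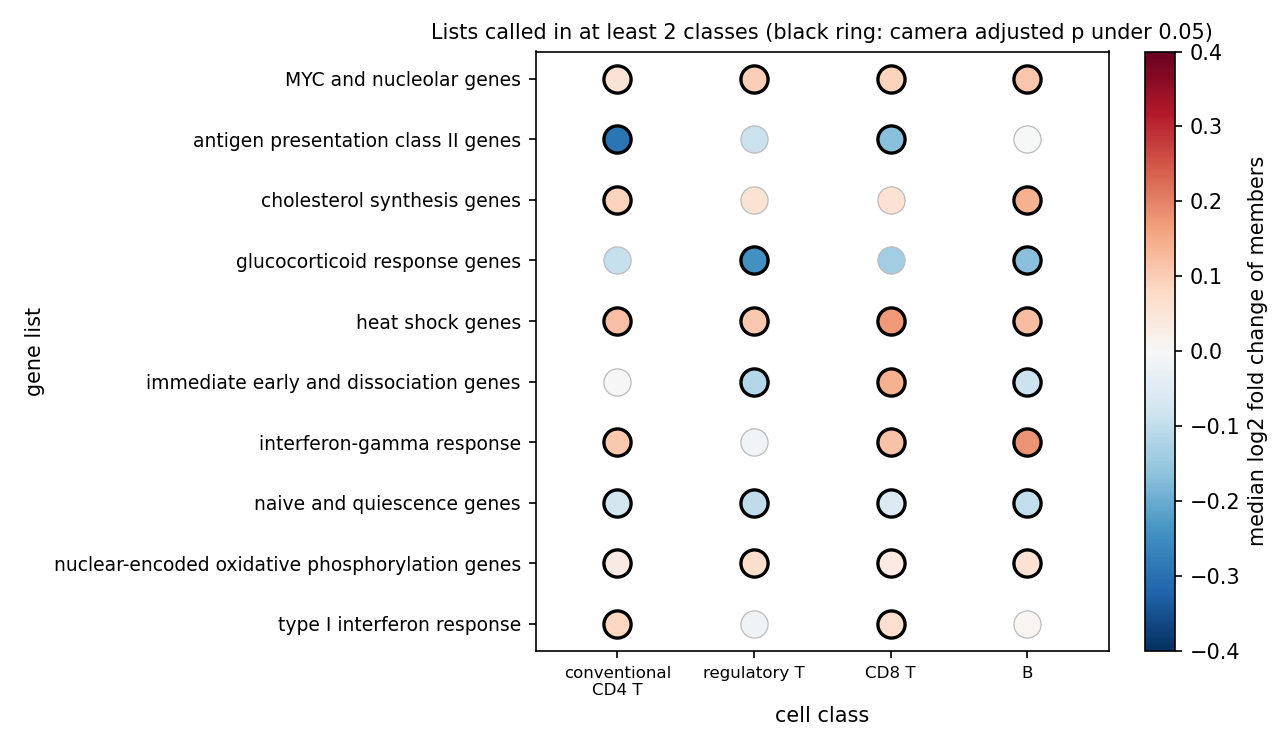
Median log2 fold change of Cre-positive over Cre-negative mice on the color scale, for the 10 gene lists that passed in at least 2 of the main classes. Each list is crossed with each of the 4 main classes, and a black ring marks a camera adjusted p under 0.05; the naive and quiescence genes were lower in all 4 classes.

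Over the 4 main classes 44 of 139 list tests passed, 24 higher and 20 lower, of which 33 were lists of pathways or cell states. With an estimated correlation 0 of the 139 passed and the smallest adjusted p was 0.451, and with fry 0 passed and the smallest was 0.158. Without Cre-negative 1 the count was 27.

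Activated or memory T cells were tested on their own. In the CD8 cells of this kind Trim59 rose from 36.4 ± 2.19 to 65.2 ± 6.45 CPM (SD, n = 3; log2 fold change 0.84, SE 0.167, adjusted p = 0.0171) and was the 1 gene of 7725 that passed, with 375 at an unadjusted p under 0.05 and 0 with DESeq2. The mRNA decapping gene Dcp1a at -0.97, Ublcp1 at 0.90, Cd24a at -1.68, Tnfaip3 at -0.36, Mbnl1 at 0.33, Gpatch11 at 0.68, Stt3b at -0.61, Rab10os at -0.63 and Tmx4 at 0.63 did not pass. Trim59 was lost without Cre-negative 1 (0.131), Cre-negative 2 (0.223) and Cre-positive 1 (0.0894), with doublets kept (0.0970), at 5% mitochondrial UMIs (0.368) and with DESeq2 (1.00). The count was 0 without Cre-negative 1 or Cre-negative 2, 2 without Cre-negative 3, 4 without Cre-positive 1 and 7 without Cre-positive 3. In the CD4 cells of this kind edgeR passed 0 of 8043 genes, with 336 at an unadjusted p under 0.05 and 0 with DESeq2, and the count was 2 without Cre-negative 1 or Cre-positive 1 and 1 without Cre-positive 2. The immediate early gene Egr1 stood at 633 ± 107 and 421 ± 82.2 CPM (adjusted p = 0.434) and passed without Cre-positive 2 (0.0110, in a range from 3.54e-04 to 1.00), while Egr2 had a log2 fold change of -0.63, Jun of -0.37, Tsc22d1 of -1.58, Mbnl1 of 0.39, H2-Q4 of -0.49, Stard5 of -0.73, Pgrmc1 of -0.69, Mbnl2 of -0.46 and Mir142hg of -0.78. The groups did not overlap for 9.83% of genes in the CD8 and 9.32% in the CD4 cells, where chance gives 10%. Foxp3 in the activated or memory CD4 cells stood at 49.4 ± 7.27 CPM in Cre-negative and 50.4 ± 13.3 CPM in Cre-positive mice. In all conventional CD4 T cells it had 4.72 and 6.45 CPM, and in regulatory T cells 255 and 252 CPM. So regulatory T cells among the activated or memory CD4 cells are not excluded.

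The genotype effect differed between conventional CD4 and CD8 T cells for 10 of 11553 genes, with 718 (6.21%) at an unadjusted p under 0.05. Pmepa1 had a larger effect in CD4 cells, with log2 fold changes of 0.60 and 0.17 (difference 0.43, adjusted p = 0.00265), and so did Mycbp2, a ubiquitin ligase gene, with 0.19 and -0.06 (0.25, 4.19e-05). Trim59 had a larger effect in CD8 cells, with 0.34 and 0.70 (-0.35, 0.0463). The differences for Tnfaip3 (0.211) and Gh (0.334) did not pass. Gh had 0, 5 and 0 UMIs in CD8 T cells of Cre-positive mice 1 to 3, against 140, 234 and 262 in conventional CD4 T cells. With counts at or near 0 in CD8 T cells, its test does not show that the effects are alike. The count was 16 without Cre-negative 2, 18 without Cre-positive 1 and 6 without Cre-positive 2. Between conventional CD4 T and B cells 3 of 12066 genes differed, with 636 (5.27%) at an unadjusted p under 0.05. The 3 were Gh, H2-Eb1 (log2 fold changes -0.33 and 0.02) and the heat shock gene Hspa1a (0.07 in conventional CD4 T cells). That count was 7 without Cre-negative 3 and 1 without Cre-positive 3. Tnfaip3 (adjusted p = 1.00), Kpna4 (0.962) and Mbnl1 (0.993) did not differ detectably between these classes.

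The shares of the main cell types overlapped between the groups. T cells were 70.3% ± 1.2 of Cre-negative and 67.9% ± 5.28 of Cre-positive cells (SD, n = 3, exact permutation p = 0.4), and B cells 21.2% ± 0.866 and 25.6% ± 6.79 (exact p = 0.4). CD8 T cells made up 29.5% ± 1.37 and 30.9% ± 3.09 of CD4 and CD8 T cells (exact p = 0.5). Regulatory T cells were 12.8% ± 0.429 and 12.1% ± 2.28 of CD4 T cells (exact p = 0.6). Activated or memory cells were 7.13% ± 1.25 and 8.53% ± 2.74 of conventional CD4 T cells (exact p = 0.6) and 9.59% ± 1.44 and 11.1% ± 1.25 of CD8 T cells (exact p = 0.2). With 3 mice against 3 the test cannot give a p below 0.1.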

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

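The comparison of Gh between CD4 and CD8 T cells as a test of free RNA was chosen after the result was seen, while the test on T cells outside the named classes was written before its result was.

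Gh stood out for a genotype effect that differed between conventional CD4 T and B cells, with a difference of log2 effects of 9.95 (SE 0.962, adjusted p = 4.67e-07) that depends on the handling of counts of 0 and is no measure of its size. It was also found in cells that no comparison used: among Cre-positive T cells outside the named classes with a Cd4 and no Cd8 UMI, 35 of 562 had a Gh UMI (6.23%), against 0 of 548 in Cre-negative mice. Free RNA from other cells is argued against, since 0.0958% of Cre-positive CD8 T cells (5 of 5217, median 5813 UMIs) had a Gh UMI against 6.05% of conventional CD4 T cells at a lower median of 4761. These are shares over cells. Over mice, the interaction test of Gh between these classes did not pass (adjusted p = 0.334), with counts at or near 0 in CD8 T cells. A transcript of the CD4-Cre transgene is a candidate explanation, since growth hormone gene sequence is used in transgene constructs: the share of 6.23% in the unnamed cells with Cd4 compares with 0.709% (2 of 282) in those with Cd8, a ratio of 8.78 (Fisher's exact p = 5.56e-05 over cells, which are not replicates; median depths 5092 and 5790 UMIs), and the transgene sequence was not analysed here. An effect of the deletion on the endogenous gene stays open. CD4-Cre is used to delete in the CD8 lineage as well, so such an effect would have to act in CD4 and hardly in CD8 T cells, and the deletion was not measured cell by cell.

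Between conventional CD4 T and B cells the effect also differed for H2-Eb1, by -0.35 (SE 0.0564, adjusted p = 0.0101). H2-Eb1 is one of the class II genes, which were lower in conventional CD4 T cells together with B cell markers. Free RNA from other cells was not tested as their source, so the difference is not shown to arise within T cells. The effect differed for Hspa1a by 2.29 (SE 0.429, adjusted p = 0.0339), a gene too low to be tested in B cells alone. In conventional CD4 T cells its log2 fold change was 0.07, so the difference is no measure of a rise there. Between conventional CD4 and CD8 T cells the effect was higher in CD4 cells for Mycbp2, by 0.25 (SE 0.0413), and for Pmepa1, by 0.43 (SE 0.0832). It differed for the cytotoxic granule gene Gzmb by 3.58 (SE 0.694), a gene too low to be tested in CD4 cells alone. Gzmb had a log2 fold change of -1.33 in CD8 T cells, so its difference is no measure of a rise in CD4 cells. The effect in CD4 minus that in CD8 cells was -0.35 for Trim59 (SE 0.0837), -0.13 for Lef1 (SE 0.0293) and -0.06 for the ribosomal protein gene Rplp1 (SE 0.0138). For the unnamed transcripts Gm26917, Gm26825 and 2900060B14Rik it was -0.26 (SE 0.0533), -0.39 (SE 0.0902) and -0.60 (SE 0.130). Adjusted p of these 9 genes lay between 4.19e-05 and 0.0463.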

How the results depend on the processing

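The alternatives with cells of both Cd4 and Cd8 UMIs kept, without the immediate early clusters and without 1 B cell cluster were chosen after the data were seen. For the 9 pairs of a gene and class that passed, 121 of 155 alternative values stayed past the threshold, 34 did not, and 0 changed direction. For the 52 named pairs that did not pass and are reported here, 30 of 854 alternative values passed and 0 changed direction. Counts of genes past the threshold moved by more than 1.5 times under several settings, and the cause was not tested. Leaving out a mouse gave 1 to 14 genes in conventional CD4 T cells, 1 to 4 in regulatory T cells, 1 to 11 in CD8 T cells, 0 to 6 in B cells, 0 to 2 in activated or memory CD4 and 0 to 7 in activated or memory CD8 T cells. It gave 1 to 7 genes for the difference between conventional CD4 T and B cells, 6 to 18 for that between conventional CD4 and CD8 T cells, and 27 to 48 lists. Without the low-count filter the counts were 19 (conventional CD4), 3 (regulatory), 12 (CD8), 22 (B), 5 (activated or memory CD4), 7 (activated or memory CD8) and 28 (difference between conventional CD4 T and B cells). At 5% mitochondrial UMIs they were 1 in conventional CD4, 0 in regulatory, 3 in B and 3 in activated or memory CD8 T cells, and 4 for the difference between conventional CD4 and CD8 T cells. With the same number of cells per mouse they were 4 in conventional CD4 T, 0 in B and 2 in activated or memory CD8 T cells, and with gates on single cells 1 in conventional CD4 T cells. With DESeq2 they were 5 in conventional CD4, 2 in CD8, 5 in B and 0 in activated or memory CD8 T cells. With doublets kept they were 0 in activated or memory CD8 T cells and 6 for the difference between conventional CD4 and CD8 T cells, and without the B1-like or memory-like cluster, formed with Fcrl5 among its genes, 0 in B cells. Of the 44 lists 0 passed with an estimated correlation and 0 with fry. The difference in the share of T cells was 0.407 percentage points at 5% mitochondrial UMIs against -2.47, and that of CD8 T cells -1.12 without the immediate early clusters against 1.44. Without 1 mouse the difference in the share of regulatory T cells lay between -2.02 and 0.140, and that of activated or memory CD4 T cells between -0.132 and 2.51. The smaller classes limit what can be seen, since activated or memory cells numbered 131 to 368 per mouse. With the replicate number as a block the counts were 8 in conventional CD4, 15 in CD8, 3 in B and 1 in activated or memory CD4 T cells. Those of regulatory T cells (1), activated or memory CD8 T cells (1) and lists (52) stayed within 1.5 times, and this block was not run for the differences between classes, which have the mouse as a block. The numbers were not taken to pair the mice: deviations of mice with the same number correlated between -0.152 and 0.115, those of other pairs between -0.101 and 0.178, and 6 of 18 Cre-negative sums correlated best with their own number.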

Other observations

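The tests that compared the chromosome 3 window with B cells, with other windows and with the top windows of other splits were chosen after the result was seen, and so was the window.

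Rarer cells of the node are described here as values. Conventional dendritic cells were 0.60% ± 0.0229 of cells in Cre-negative and 0.486% ± 0.0577 in Cre-positive mice (SD, n = 3, exact permutation p = 0.1, the smallest the design allows). Migratory dendritic cells, which carry antigen from the tissue, were 2.97% ± 0.331 and 2.01% ± 1.26, with 0.815% in Cre-positive 3. Most of them lay in a low-depth cluster, with 176, 235 and 240 cells in Cre-negative mice 1 to 3 and 155, 259 and 52 in Cre-positive mice 1 to 3, while the other cluster held 10, 33 and 17 and 25, 57 and 20. Gamma-delta or innate-like T cells were 0.734% ± 0.0660 and 0.549% ± 0.293, with 0.238% in Cre-positive 3. Germinal centre B cells were 0.272% ± 0.0655 and 0.358% ± 0.205.

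Genes between 60 and 70 Mb of chromosome 3 gathered small p-values in both T and B cells. In conventional CD4 T cells 5 of 24 tested genes in this window (Mbnl1, Lxn, Trim59, Kpna4 and Ppm1l) had an unadjusted p under 0.01, the strongest enrichment of 277 windows (hypergeometric p over genes 7.35e-04 after Bonferroni adjustment), and the values were 5 of 22 in CD8 T cells (0.00171), 4 of 22 in B cells (0.0254) and 3 of 21 in regulatory T cells (0.293). In activated or memory cells they were 3 of 15 for CD8 (0.0497) and 2 of 18 for CD4 T cells (1.00). Mbnl1, Tiparp, Lxn, Trim59 and Kpna4 made up the 5 in CD8 T cells. So every gene that passed in CD8 T cells but Tnfaip3 lies in this window. Trim59, the gene that passed in activated or memory CD8 T cells, does too. Mbnl1, Lekr1, Il12a and Kpna4 made up the 4 in B cells, with log2 fold changes of 0.34, -1.19, 0.35 and -0.33.

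In conventional CD4 T, regulatory T and B cells other splits of the mice gave windows as enriched when each was given its own. In CD8 T cells they did not. In conventional CD4 T cells the hypergeometric p of the most enriched window was 2.65e-06 for the real split and 2.38e-10 for the most extreme other, the split of Cre-negative 1, Cre-positive 1 and Cre-positive 2 against the rest, with 13 of 56 genes between 20 and 30 Mb of chromosome 13. That made 2 of 10 splits, the real one included, and 10 are too few for a share under 0.05. In B cells 3 of 10 did so, and in CD8 T cells 1 of 10, the real one, with 6.18e-06 against 3.32e-04 for the most extreme other. In regulatory T cells the hypergeometric p was 0.00106 for the real split and 1.03e-04 for the most extreme other. An effect of the deletion inside the T cells alone stays open: in B cells the window itself held 4 genes in the real split, where 95% of windows had at most 2, and 0 or 1 in each of the 9 others, which goes against it as the whole cause, but the splits are too few and windows elsewhere were as enriched. Inherited sequence differences linked to the genotype in this region cannot be told apart from other effects that the cells of a mouse share: log2 folds in conventional CD4 T and B cells correlated at 0.724 over 21 genes of the window, at the 98.3 percentile of 241 other windows with a median of 0.268, but either would give this, and the window was picked for its small p-values. The position of the transgene and the strain background were not in the labels.

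The other counts were recomputed for the same 10 splits, which are too few for a share under 0.05. In conventional CD4 T cells the real count was 2 and the highest other 19, with 4 splits at or above the real count, the real one included. The values were 1, 8 and 4 in regulatory T cells, 4, 9 and 3 in CD8 T cells and 1, 11 and 4 in B cells. In activated or memory cells they were 0, 8 and 10 for CD4 and 1, 6 and 8 for CD8 T cells. For the difference between conventional CD4 T and B cells they were 3, 20 and 4, for that between conventional CD4 and CD8 T cells 10, 4 and 1, and for the lists 44, 47 and 2. The highest counts in conventional CD4, regulatory, B and both activated or memory classes came from the split of Cre-negative 1, Cre-positive 1 and Cre-positive 2 against the other mice, which points to a structure of the samples that the genotype does not give where it called several times the real count, in all of these but activated or memory CD4 T cells, with 8 against 0.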
